A study of Mus musculus with 2 samples.

How the data were processed

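Messenger RNA levels were measured in 2 samples of mouse bone marrow cells on Illumina bead arrays, a platform on which each gene is read by 1 or several oligonucleotide probes and biotin-labelled cRNA gives a brightness per probe. Per the labels' protocols, marrow from the long bones of C57BL/6J mice aged 8 to 12 weeks was cultured with macrophage colony-stimulating factor (M-CSF, 25 ng/ml) for 4 days, and osteoclasts were then made by 3 further days at the same M-CSF dose plus soluble RANKL at 30 ng/ml, the cytokine that drives osteoclast formation. Each sample stood for 3 mice and was hybridised to 1 array. The labels do not say whether the macrophages were collected at the start or at the end of those 3 further days, and the sample descriptions place the arrays on different chips. Chip, any day of handling and cell type therefore cannot be told apart.

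The deposited non-normalized table gives 1 intensity per probe and array, on a linear scale. Values below 0 made up 38.4% of the macrophage array and 36.9% of the osteoclast array, so a background had been subtracted; the scanner software, the background method and the versions are not given in the sources used here. The authors' processed table gives values on a log2 scale, with medians of 5.00 and 5.05 for macrophages and osteoclasts, and how the authors normalized it is likewise not given. Across 5844 probes above an intensity of 200 on both arrays, the difference between the authors' columns followed the log2 ratio of the intensities with a slope of 0.97 and r = 0.999 across probes (probes are not independent replicates), which sets the scale to log2 and the direction to that of the intensities; its centring stays unknown. Across all probes, ranks within an array were close to those of the intensities, with a Spearman rho of 0.993 for macrophages and 0.999 for osteoclasts. The intensities were the starting point here, and the authors' values were an alternative.

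The plan, fixed before the data were examined, was limma's neqc with detection p-values, but the tables used here hold neither detection p-values nor control probes. The background of unexpressed probes was estimated for each array from the mode of its intensities and the spread below that mode. This gave -3.60 with an SD of 3.66 on the macrophage array and -5.35 with an SD of 5.40 on the osteoclast array. These values entered limma's normexp correction, an offset of 16 was added, and the arrays were quantile normalized on the log2 scale (limma 3.58.1, R 4.3.3). A probe was called detected where its intensity lay above the value that the estimated background exceeds with a one-sided p of 0.01. This limit was 4.91 on the macrophage array and 7.21 on the osteoclast array. It assumes a normal background with the spread seen below the mode. Without control probes the true rate of false detection is unknown. Of 45281 probes, 21660 (47.8%) were detected on the macrophage array and 23009 (50.8%) on the osteoclast array. Differences are osteoclast minus macrophage on the log2(corrected intensity + 16) scale, which understates the change of dim genes. Later steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

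Probes were named from the platform annotation: 34885 probes had 1 gene, 18 had several and 10378 were not listed. Entrez identifiers of 34807 probes matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. The array's build is not named, so no coordinates are given. A gene was represented by its probe with the highest mean signal over both arrays, which gave 19057 genes. Probe sets for 1 gene can read different transcript forms, and where probes of a rule-named gene that were detected on both arrays differed by over 1 log2 unit, this is stated. A gene detected on 1 array only has a bound: its bright value against the higher of its own dim value and the lowest signal of any detected probe on the other array, written as "at least N-fold". Counts by the size rule use the measured difference of all detected genes, and counts at their bounds are given where they differ.

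With 1 array per group there is no spread between samples, so no test was run and no p-value is given. Genes were counted by a rule of size, at least 2-fold apart and detected on at least 1 array. For each of 27 gene lists fixed before the data were examined, with 516 entries of which 472 were measured, the median difference of its detected members was placed among the medians of 10000 random lists of the same size, matched on mean signal in 10 bins; the central range is the middle 95% of them, and the percentile describes these 2 arrays and not the conditions. Named genes followed a rule fixed in advance: the 12 genes with the largest difference in each direction among those detected on both arrays, the 5 with the largest bound in each direction, up to 4 members per list with the largest differences, and 10 preset genes, of which 1 is not reported here. Other genes named in the text were chosen after their values were seen. Technical precision between arrays cannot be gauged. Among 3849 genes with at least 2 probes detected on both arrays, the pooled SD of the log2 difference between probes of a gene was 0.43. This spread can also hold differences between transcript forms, and it does not measure error between replicate samples.

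The steps were tested on simulated data: a copy of the macrophage array, made brighter by the observed ratio, with 200 probes changed by known folds among 45281 and an assumed noise of 0.15 log2 units per array. The changed probes, 25 per fold and direction, were well above the upper quartile of the macrophage array (39.6), without the brightest. All of those changed 4-fold, 8-fold or 16-fold passed the 2-fold rule (100% in each direction), which does not cover dim probes. Of those raised 2-fold 44% passed, and of those lowered 2-fold 52%. Of 22151 unchanged detected probes 0.0226% passed, a share that holds for the assumed noise only. That noise was not estimated from these arrays. Far fewer probes changed than in the data, so the normalization was not tested at the real share of changes. For a true 16-fold change the median log2 size was 3.85 for raised and 3.45 for lowered probes. The alternatives covered the background correction (left out together with the offset, values under 1 being set to 1), the offset, the normalization between arrays, the authors' values, the detection limit, the choice of probe and the size rule. List medians under alternatives are given after removing the shift of all genes, except where a sign that turns with the scaling is stated, which is the value before removal. 4 alternatives and 9 further marker lists were added after seeing the data.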

Results

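The series compared bone marrow macrophages, grown with M-CSF, with osteoclasts, the multinucleated bone-resorbing cells that form from the same precursors when RANKL is added. There was 1 array per cell type, each of a sample from 3 mice, and no replicate array, so every difference below is between these 2 samples and has no replicate check. The median probe intensity was 3.90 on the macrophage array and 7.84 on the osteoclast array, and the upper quartiles were 39.6 and 81.7. Among probes detected on both arrays, the median of the background-corrected intensity plus the offset was 1.76 times higher on the osteoclast array. This was before normalization between arrays. Of 19057 genes, 13003 were detected on at least 1 array: 10494 on both, 1567 on the osteoclast array only and 942 on the macrophage array only.

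The osteoclast sample was set apart by cathepsin K and other genes of bone resorption and by genes of epidermis and skeletal muscle, and the macrophage sample by granule proteins of neutrophils and by macrophage receptors. List medians were 2.65 log2 units for resorption genes, and 3.38 for epidermal and 3.12 for muscle genes, both listed after seeing the data. At least 2-fold higher in the osteoclast sample were 1500 genes, and 1067 were at least 2-fold lower, while 10436 (80.3%) lay within 2-fold. At least 8-fold differences numbered 182 higher and 101 lower genes. With genes detected on 1 array only at their bounds, 1364 were at least 2-fold higher and 1010 lower, and 161 and 99 at least 8-fold. The largest difference of a gene detected on both arrays was that of Ctsk (cathepsin K, the protease that degrades bone collagen; Entrez Gene 13038), at 425-fold higher, from an intensity of 55.4 in macrophages to 50206 in osteoclasts. Next came Oscar (the osteoclast-associated receptor, 68.3-fold), F2r (a thrombin receptor, 65.6-fold), Arsb (the lysosomal arylsulfatase B, 62.7-fold), Cav1 (caveolin 1, 59.1-fold), Bdh1 (a ketone body dehydrogenase, 42.8-fold) and Mmp9 (a gelatinase, 41.1-fold). A second probe of Arsb differed by 2.12, and a further one, detected on the osteoclast array only, allowed no fold. The other probe of Bdh1 differed by -0.09, so its call rests on 1 probe. The 12 genes also held Atp2a1 (the calcium pump of fast muscle fibres, 37.6-fold), Krt10 (a keratin of the upper epidermis, 36.5-fold), Cd109 (31.9-fold), Acp5 (tartrate-resistant acid phosphatase, the histochemical marker of osteoclasts, 30.8-fold) and Rai14 (29.0-fold). Among genes not detected on the macrophage array, the largest bounds were those of Bdh2 (at least 274-fold higher), Mt3 (a metallothionein, at least 217-fold), Slc9b2 (a sodium-proton exchanger, at least 206-fold), Lor (loricrin of the cornified skin layer, at least 152-fold) and Acta1 (skeletal muscle actin, at least 134-fold).

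In the other direction, granule and secreted proteins of neutrophils led the 12 genes with the largest differences. Ngp (neutrophilic granule protein) was 194-fold lower in the osteoclast sample, Ltf (lactotransferrin) 162-fold, S100a9 105-fold, Lcn2 (lipocalin 2) 92.6-fold, Fpr2 (a formyl peptide receptor) 89.7-fold, Camp (cathelicidin) 81.3-fold and S100a8 51.3-fold. The others were the chitinase-like genes Chil4 (80.6-fold) and Chil3 (55.7-fold), Fcrls (62.6-fold), Cyp27a1 (sterol 27-hydroxylase, 30.5-fold) and F13a1 (coagulation factor XIII, 23.5-fold). The other probe of Ltf, not well above background in osteoclasts, was at least 6.48-fold lower. Not detected on the osteoclast array were Mpo (myeloperoxidase, at least 52.9-fold lower), Retnlg (at least 48.8-fold), Ifit1bl1 (at least 16.7-fold), Cyp4f18 (at least 16.3-fold) and Rapsn (at least 14.6-fold). The other probes of Mpo gave bounds down to at least 3.62-fold lower, and that of Cyp4f18 at least 5.61-fold. The split between directions depended on the scaling. Median scaling gave 1309 higher and 1740 lower genes (42.9% higher against 58.4%), and without normalization 3839 were higher and 374 lower (91.1% higher), where the median difference of all detected genes lay 0.64 log2 units above that after quantile normalization (-0.17 under median scaling).

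**Figure D1:**
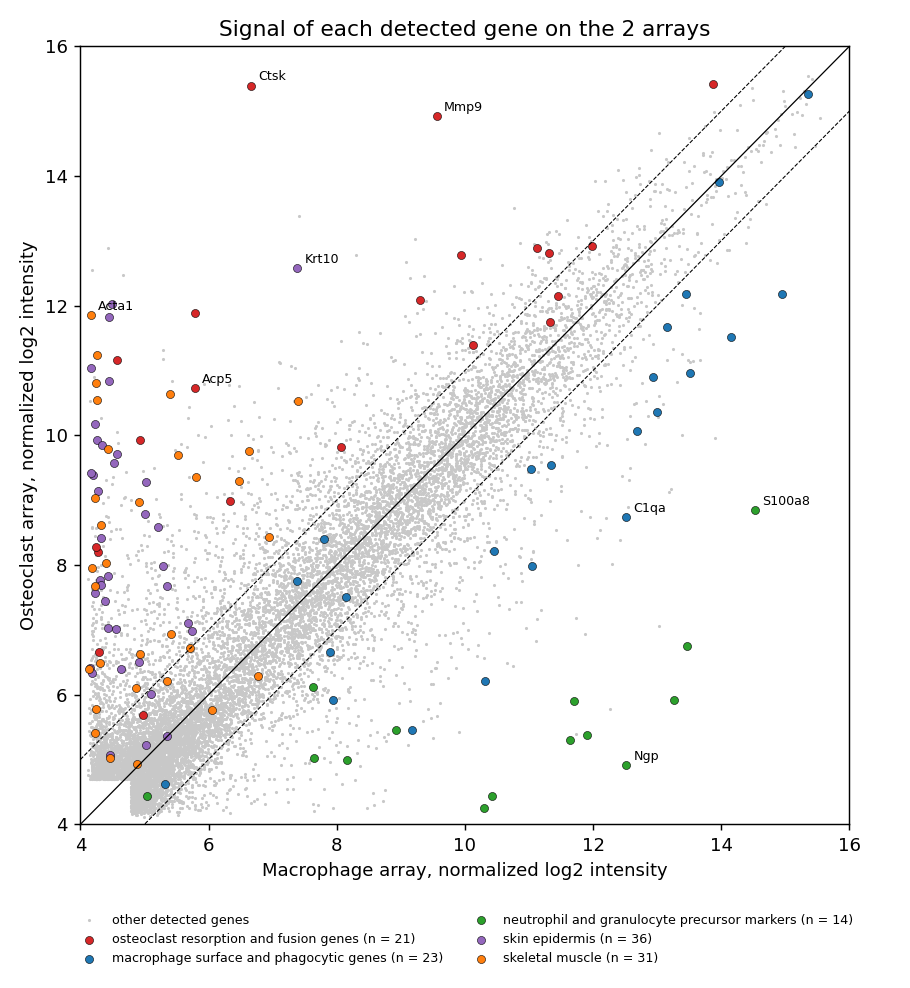
Normalized log2 intensity of each of the 13003 detected genes on the macrophage array (x axis) and the osteoclast array (y axis), with members of 5 gene lists coloured; the solid line marks equal signal and the dashed lines a 2-fold difference, and each point is 1 gene on 1 array per cell type. Ctsk lies 425-fold above equality and Ngp 194-fold below it, and many epidermal and muscle genes lie at the left edge, where the macrophage array was near background.

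Genes that carry out bone resorption and cell fusion were higher in the osteoclast sample. Of 21 detected members of this list, 17 were at least 2-fold higher, 0 were 2-fold lower and 4 lay within 2-fold, and all 21 differences were above 0. The median was 2.65 log2 units (6.27-fold), at percentile 100 of the random lists. Besides Ctsk, Oscar, Mmp9 and Acp5, Dcstamp (a fusion protein of osteoclast precursors) was at least 83.4-fold higher and Calcr (the calcitonin receptor) at least 3.68-fold, both undetected in macrophages. Atp6v0d2, a proton pump subunit of osteoclasts, was not well above background on either array. Counting only genes detected on both arrays gave a median of 1.76, and averaging all probes of a gene gave 1.52.

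Subunits of the vacuolar proton pump, which acidifies the resorption pit, had a median difference of 0.91 (1.88-fold, percentile 100). Of 16 detected subunits 7 were at least 2-fold higher, 0 were lower and 9 lay within 2-fold. The largest differences were those of Atp6v1h (3.64-fold higher), Atp6v1b2 (3.23-fold), Atp6v1d (3.08-fold) and Atp6v1c1 (3.04-fold). The second probe of Atp6v1h, not well above background in macrophages, was at least 1.06-fold higher.

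The list of RANK signalling components and osteoclast transcription factors did not stand apart as a whole. It had a median of -0.13 at percentile 29.9, with 7 of 30 detected members at least 2-fold higher, 0 lower and 23 within 2-fold. Jdp2 (a partner of AP-1 factors) was 19.5-fold higher, the kinase gene Src 11.5-fold, Fosl2 (a Fos family factor) 9.53-fold and Ppargc1b (a coactivator of mitochondrial biogenesis) 7.24-fold. Tnfrsf11a, which encodes the RANKL receptor RANK, was 4.10-fold higher. A second detected probe of Src differed by -0.18 and that of Fosl2 by -0.51, so the calls at the probes chosen for these genes are not shared by all their probes. Nfatc1, the main transcription factor of osteoclast differentiation, differed by -0.02 at the probe that stands for the gene, and by 0.77 there without normalization, and its 6 probes ranged from -0.72 to 3.15. The probe at 3.15 (8.90-fold higher) had intensities of 8.42 in macrophages and 371 in osteoclasts, and that standing for the gene had 674 and 1165.

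Genes known to restrain osteoclast formation went both ways, with a median of 0.09 at percentile 66.2 (0.03 with genes at their bounds). Of 10 detected members 3 were at least 2-fold higher, 1 was lower and 6 lay within 2-fold. Irf8, a transcription factor of the macrophage lineage, was 10.1-fold lower in the osteoclast sample. Id1 was at least 5.99-fold higher, Id3 2.25-fold and Egr2 2.15-fold.

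Macrophage surface receptors and phagocytic genes were lower in the osteoclast sample. Of 23 detected members 17 were at least 2-fold lower, 0 were higher and 6 lay within 2-fold, and the median was -2.02 (4.05-fold lower, percentile 0). Fcgr1, a high-affinity receptor for IgG, was 17.2-fold lower, C1qa (a complement C1q chain) 13.7-fold, the scavenger receptor gene Marco 13.3-fold and Fcgr2b 8.40-fold. Csf1r, which encodes the M-CSF receptor, was 2.80-fold lower and Adgre1, which encodes the F4/80 antigen, 2.41-fold lower. The probes of Fcgr2b ranged from -3.07 to -0.17. Markers of granulocytes, some of which carry Fc receptors too, were also lower, with a list median of -5.89.

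Toll-like receptors and their signalling genes were lower as well, with a median of -0.88 (1.84-fold lower, percentile 0; -0.74 with genes at their bounds) over 19 detected members. Without background correction the median was -1.84. At least 2-fold lower were 8 members, or 7 at their bounds (Nlrp3 differed by -0.58 at its bound), 0 were higher and 11 lay within 2-fold. The granulocyte list, whose cells are known to express several of these receptors, had a median of -5.89. Irak3 was 7.22-fold lower, Tlr2 5.20-fold, Tlr1 4.89-fold and Tlr8 4.51-fold. Of 13 genes of MHC class II and antigen presentation, 10 were at least 2-fold lower, 1 was higher and 2 lay within 2-fold, with a median of -2.89 (7.40-fold lower, percentile 0). Averaging the probes of a gene gave -1.84. H2-DMa was 15.2-fold lower, H2-Ab1 13.7-fold, the costimulatory gene Cd86 10.9-fold and H2-Aa 10.8-fold. The exception was Ifi30, the lysosomal thiol reductase, with a difference of 1.83. Dendritic cell markers had a median of -0.34 (percentile 13.5; -0.30 with genes at their bounds), which was 0.05 without normalization and -1.15 without background correction. Of 7 detected members 2 were 2-fold lower, or 1 at its bound, Batf3 (at least 10.5-fold, and at least 4.40-fold at its other probe); Siglech was at least 1.65-fold lower, and 5 lay within 2-fold. Flt3 was at least 1.23-fold lower, and Ccr7 differed by -0.34, or by 0.20 without normalization.

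Interferon-stimulated genes were lower in the osteoclast sample, with a median of -1.63 (3.10-fold lower, percentile 0). Of 22 detected members 17 were at least 2-fold lower, or 16 at their bounds (Ifih1 was at least 1.76-fold lower), 0 were higher and 5 lay within 2-fold. Ifit2 was 19.4-fold lower, Ifit3 and Gbp2 12.6-fold each and Rsad2 9.30-fold. The other detected probe of Ifit2 differed by -3.25 and that of Gbp2 by -2.63. Chemokines and cytokines had a median of -1.32 (2.50-fold lower, percentile 0), with 12 of 21 detected members 2-fold lower, 2 higher and 7 within 2-fold. Ccl5 was 22.5-fold lower, Il1b 11.1-fold, Cxcl9 6.03-fold and Il10 6.00-fold. The 2 higher members were Ccl8 (1.89) and Il1rn (1.85), the antagonist of interleukin 1. Neutrophils are a known source of Il1b, and the granulocyte list had its median of -5.89 in the same direction.

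Genes of energy metabolism were higher in the osteoclast sample. Oxidative phosphorylation genes had a median of 0.95 (1.93-fold, percentile 100); 13 of 33 detected members were at least 2-fold higher, 0 were lower and 20 lay within 2-fold, and 32 differences were above 0. Cycs (cytochrome c) was 4.68-fold higher, Cyc1 4.55-fold, Uqcrc1 2.58-fold and Ndufa4 2.38-fold. The probes of Cycs ranged from 0.18 to 2.23. In the list of the citric acid cycle and mitochondrial biogenesis, 5 of 16 detected members were higher, 1 was lower and 10 lay within 2-fold, with a median of 0.73 (1.65-fold, percentile 99.9). Idh3a (an isocitrate dehydrogenase subunit) was 9.01-fold higher (1.53 log2 units at its other probe), Mdh2 (malate dehydrogenase) 6.12-fold and Cs (citrate synthase) 3.19-fold, and the lower gene was Nrf1 (-1.05). Glycolysis genes had a median of 0.95 (1.93-fold, percentile 99.97), with 7 of 15 higher, 0 lower and 8 within 2-fold. Ldha (lactate dehydrogenase A) was 2.56-fold higher, Tpi1 2.32-fold, Pgk1 2.30-fold and Aldoc 2.69-fold, although the other detected probe of Aldoc differed by -0.50. Skeletal muscle genes, of a tissue rich in these enzymes, were higher in the same sample with a median of 3.12.

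The medians of the cholesterol synthesis, lipid handling and lysosome lists lay inside the central range of the random lists. Members of the lipid handling and lysosome lists differed in both directions. None of 15 detected cholesterol synthesis genes (0) reached 2-fold, with a median of -0.20 (percentile 26.3); Cyp51 differed by -0.93, Mvd by -0.78, Insig1 by -0.65 and Sqle by -0.52. Without normalization the last 3 were 0.09, 0.22 and 0.27 and this median was 0.51, and those of lysosomal genes, lipid handling and RANK signalling were also above 0, at 0.46, 0.71 and 0.63. Among 13 genes of cholesterol efflux and lipid handling (median -0.08, percentile 41.9, and 0.04 with cyclic loess), 2 were higher, 3 lower and 8 within 2-fold. Apoc2 was 13.2-fold (its other probe at -0.63) and Apoe (apolipoprotein E) 6.78-fold lower, whereas Nr1h3 (the nuclear receptor LXR alpha) was 5.53-fold and Lpl (lipoprotein lipase) 2.02-fold higher. Of 21 lysosomal genes (median -0.22, percentile 12.2) 1, Ctsk, was higher, 5 were lower and 15 lay within 2-fold. Ctsh (cathepsin H) was 5.35-fold lower, the protease gene Lgmn 3.42-fold and the membrane protein gene Scarb2 3.16-fold.

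Cell cycle genes were higher in the osteoclast sample: 20 of 22 detected members were at least 2-fold higher, 0 were lower and 2 lay within 2-fold. The median was 2.50 (5.66-fold, percentile 100). Birc5 (survivin) was 12.4-fold higher, the mitotic kinase genes Aurka 10.9-fold and Plk1 10.5-fold, and Mcm5, of the replicative helicase, 10.5-fold. Averaging the probes of a gene gave a median of 1.91. Epidermal, muscle and fibroblast genes were higher in the same sample, with medians of 3.38, 3.12 and 1.77.

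Of 23 podosome and actin genes (median 0.03, percentile 63.4), 4 were higher, 0 lower and 19 within 2-fold. Actn1 (alpha-actinin) was 4.13-fold higher, Vcl (vinculin) 2.51-fold, Dock5 at least 2.75-fold and Myo1d at least 2.34-fold, with another probe of Myo1d at least 1.10-fold higher. Median scaling turned this list's median to -0.18. Among factors by which osteoclasts act on other bone cells, 5 of 12 detected were higher, or 3 at their bounds, 1 was lower and 6 lay within 2-fold, with a median of 0.52 (1.44-fold, percentile 98.5). It was 0.33 with genes at their bounds and 1.26 without background correction. The 0.33 lies within the central range of the random lists, which was drawn from measured differences and not from bounds. Sphk1 (sphingosine kinase) was at least 18.9-fold and Pdgfa 3.04-fold higher, Pdgfb was higher by 4.00 log2 units, and Igf1 was 4.40-fold lower. Cthrc1 was at least 1.58-fold and Lif at least 1.51-fold higher. Fibroblast and epidermal genes, listed after seeing the data, were higher in the same sample too (medians 1.77 and 3.38). The call of Sphk1 rests on 1 of its 3 probes, since another detected on the osteoclast array only allowed no fold and the last was detected on neither. Another probe of Pdgfb, not well above background in macrophages, was at least 2.89-fold higher. Stress genes went both ways, with 6 of 18 higher, 4 lower and 8 within 2-fold and a median of 0.31 (percentile 94.9). Hspb1 was 6.62-fold higher at 1 probe, while its other probe, detected on the osteoclast array only, allowed no fold. Hsph1 was 4.13-fold and the phosphatase gene Dusp1 3.34-fold higher, and the immediate early gene Ier3 was 11.1-fold lower.

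Among markers of other cells that marrow cultures can hold, only the granulocyte list stood clearly apart from the random lists. Granulocyte markers were lower in the osteoclast sample, 13 of 14 at least 2-fold and 1 within 2-fold, with a median of -5.89 (59.4-fold lower, percentile 0; -5.70 with genes at their bounds). The median was -6.70 without background correction and -4.92 with an offset of 50. On the macrophage array S100a8 had an intensity of 19536 and S100a9 of 9164, against 595 and 124 on the osteoclast array. B cell markers had a median of -0.75 (percentile 1.16) over 5 detected genes. It was -0.54 with genes at their bounds and -2.01 without background correction. The -0.54 lies inside the central range of the random lists, which was drawn from measured differences and not from bounds. Cd79b was 5.14-fold lower, Vpreb3 at least 1.19-fold lower, and Cd22 (-0.77) and Ebf1 (-0.54, or 0.13 without normalization) lay within 2-fold. Of 4 detected T and NK cell markers (median -0.12, percentile 37.3) Nkg7 was at least 2.70-fold lower, and Zap70 (at least 1.09-fold higher, -0.16 under median scaling), Cd2 (-0.20) and Klrb1c (-0.04) lay within 2-fold. Without normalization this median was 0.27, Cd2 was 0.17 and Klrb1c 0.36, with Klrb1c at 0.01 in the authors' values. A stricter detection limit left Nkg7 alone, and the median was then its value, -1.79. Erythroid markers had a median of -0.36 (percentile 12.5, and -0.28 with genes at their bounds) over 6 genes. It was 0.15 without normalization and 0.94 with a stricter detection limit, which left few of the 6. Hba-a1 (alpha globin) was 4.63-fold higher, and Gata1 (at least 1.55-fold lower), Hbb-b2 (at least 1.18-fold lower) and Car1 (-0.40) lay within 2-fold. Over 8 detected mast cell, basophil and megakaryocyte markers (median 0.10, percentile 66.5), the median was -0.35 under median scaling, -0.21 without background correction and 0.78 for genes detected on both arrays. At least 2-fold differences were 2 higher, or 1 at its bound, and 2 lower. Ppbp was at least 8.59-fold and Gp9 at least 2.07-fold lower, and Fcer1a was at least 1.75-fold and Vwf 2.16-fold higher.

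Stromal and osteoblast markers had a median of 0.27 (percentile 88.6) over 9 detected genes. At least 2-fold higher were 4, or 3 at their bounds, and 5 lay within 2-fold. Dcn (decorin) was at least 44.7-fold higher, and at least 6.87-fold at another probe, Lum (lumican) at least 3.73-fold, Col1a1 at least 3.24-fold and Col3a1 at least 1.52-fold. Epidermal genes, listed after seeing the data, were at least 2-fold higher in 32 of 36 detected cases and skeletal muscle genes in 26 of 31 (32 and 24 at their bounds), with medians of 3.38 and 3.12 (3.01 and 2.89 with genes at their bounds). Common reference genes had a median of 0.31 (percentile 89.8), with Pgk1 2.30-fold higher and Gapdh (0.90), Ppia (0.79) and Ywhaz (0.46) within 2-fold. Of the 27 lists, 14 had medians outside the central range of the random lists (the middle 95%). Genes drawn independently would put 1.35 there, but members of a list can change together and some lists share members. The count is therefore no test, and with 1 array per group it says nothing about chance between samples. Among the 14, B cell markers and osteoclast-derived factors had medians inside that range with genes at their bounds. The range was drawn from measured differences, and random lists with genes at their bounds were not drawn.

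**Figure D2:**
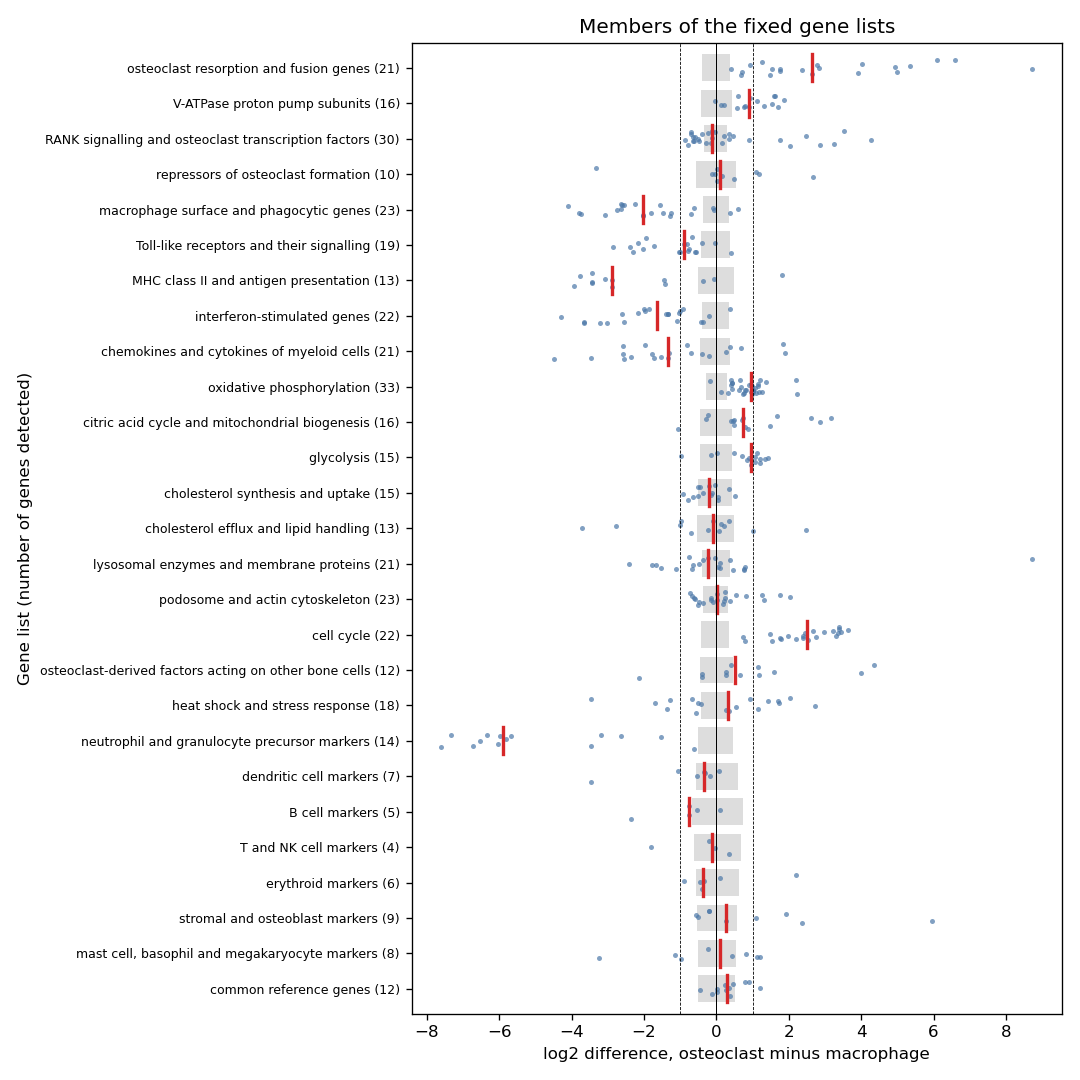
Log2 difference, osteoclast minus macrophage (x axis), of every detected member of the 27 fixed gene lists (y axis, number of genes in parentheses); points are genes, red bars list medians, grey bands the central range of medians of matched random lists and dashed lines 2-fold. In the values plotted, the granulocyte list has the lowest median, -5.89, and the resorption list the highest, 2.65. With the mean of all probes of a gene, the cell cycle median (1.91) was above that of resorption (1.52).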

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

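Probes that the annotation ties to no single gene were left out of the comparison above and also carried signal: 253 of them were detected on the osteoclast array and at least 2-fold brighter there than on the macrophage array, out of 4434 such probes detected on at least 1 array. Another 246 were at least 2-fold lower on the osteoclast array. Both are smaller shares than among named genes (1500 and 1067 of 13003), which were counted by gene, at the brightest probe, and not by probe. Outlying samples were not looked for, since each cell type had 1 array.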

How the results depend on the processing

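No replicate could be left out and no paired analysis was possible because each cell type had 1 array; precision is limited by that number, and by signal over background for dim genes. The genes called at least 2-fold higher (1500) and lower (1067) numbered 2816 and 2552 without background correction, a setting that also leaves out the offset, so which of the choices moved the counts was not tested. Without normalization they were 3839 and 374, and under median scaling 1309 and 1740; after removing the shift of all genes (0.64 and -0.17 log2 units), each gave 1606 and 1228. A 4-fold rule gave 482 and 282 genes and a 1.5-fold rule 2716 and 2649. Among the other settings, counts stayed within 1.5 times: an offset of 50 gave 1029 and 739, the mean of all probes 1125 and 788, detection on both arrays 1055 and 937, and the authors' values 1523 and 939, which shared 1451 and 886 genes with the main result. Looser or no detection limits changed neither count, so they tell nothing about stability. Chosen after seeing the data, a normexp fit to all probes gave 1343 and 902, cyclic loess 1583 and 924, and a stricter limit 1500 and 1056. Leaving out the listed skin, muscle, fat and fibroblast genes, also chosen then, gave 1425 and 1067. Those lists are too short to move a count past 1.5 times, and unlisted genes of these tissues stayed in. That setting therefore does not measure how far such tissue affects the counts. With the shift of all genes removed, no list with a median outside the central range and no named gene past 2-fold changed direction under any setting run. Under all alternatives 311 values of list medians stayed within 1.5 times and 13 moved further, among them that of the Toll-like receptor list without background correction (-1.84) and that of the resorption list with detection on both arrays (1.76) and with the mean of all probes (1.52). For named genes 1471 values stayed within it and 134 moved further, and the cause was not tested. The detection settings cannot move a gene's own value. Of the 1471, the 137 (looser limit), 137 (no limit), 106 (both arrays) and 129 (stricter limit) therefore tell nothing about stability. With the shift removed, median scaling and no normalization give the same differences, for lists too, and are not separate checks.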

Other observations

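Transcripts of epidermis and skeletal muscle were present on the osteoclast array, and the marker lists and tests in this part were all chosen after the data had been seen. Of 36 detected epidermal genes 32 were at least 2-fold higher than on the macrophage array, at their bounds too (median 3.38), with 24 of the 36 detected on the osteoclast array only and 12 on both. Krt14, the keratin of basal keratinocytes, had an intensity of 4602 against -0.22, Krtdap 2727 against -9.00 and Lgals7 1484 against -6.02. Of 31 muscle genes, 16 of them detected on both arrays, 26 were at least 2-fold higher (24 at their bounds; median 3.12), with Myl1 at 3079 against -4.44, Tnnc2 at 1933 against -4.91 and Pvalb (parvalbumin) at 1153 against -0.52. Fat genes had a median of 0.55, with Car3 at 456 against -5.95 and Adipoq at 177 against 0.27, and fibroblast genes a median of 1.77 (0.36 and 1.21 with genes at their bounds), of which 5 members are in the fixed lists. Genes of brain, liver, testis and intestine, the comparator tissues, had medians of -0.54, 0.33, -0.35 and 0.07 (-0.19, 0.29, -0.19 and 0.07 with genes at their bounds).

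A candidate explanation for this pattern is RNA or cells of skin and underlying muscle in the osteoclast sample or its labelled cRNA. The 46 detected epidermal and muscle genes that had not been seen among the extremes at the first look had a median difference of 2.26 (quartiles 1.24 and 3.38; 1.70 with genes at their bounds). The median was 0.04 over the 28 detected genes of the comparator tissues, out of 75 measured. A general rise of tissue-restricted genes is argued against, since 10.7% of those comparator genes were at least 2-fold higher against 80.4% of the held-out genes (3 and 35 genes at their bounds). Normalization is argued against as well, because the held-out median without it, less the shift of all genes, was 2.06. Expression by the cultured cells themselves was not tested and stays open, as do the step and the source of any admixture.

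Granulocyte transcripts on the macrophage array form the other pattern. A second list, without the genes seen at the first look, had a median of -1.51 over 22 detected genes (quartiles -2.62 and -0.90). It was -1.48 with genes at their bounds, and 15 genes were at least 2-fold lower in the osteoclast sample (14 at their bounds). Granulocytes and their precursors remaining in the macrophage culture would give such a fall. Macrophage surface genes were lower too, with a median of -2.02. That list was whole, while the -1.51 leaves out genes seen at the first look, so their sizes cannot be ranked. The held-out median alone does not single out granulocytes. Of the whole second list, 18 of 25 detected genes were at least 2-fold lower (17 at their bounds) and 1 was higher, with a median of -2.08, 17 were detected on the osteoclast array too, and the fixed lists share 5 members with it. Whether lymphoid and erythroid marrow cells remained beside them cannot be told apart, because their markers (median -0.40 over 15 genes) had a median intensity of 10.5 on the macrophage array, close to background. Expression of these genes by the macrophages, and a difference in culture time between the samples, were not tested.

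The probes of Nfatc1 disagreed. The 3 annotated to 1 transcript form were flat or lower (-0.02, -0.20 and -0.65), and those annotated to another gave 3.15 and -0.72, with another not well above background in macrophages (at least 1.35-fold higher). Of 32 named genes with at least 2 probes detected on both arrays, 12 had such probes that differed by over 1 log2 unit and 5 had them in both directions.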
